A study of Mus musculus with 12 samples.

How the data were processed

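RNA was measured in 12 libraries of a mouse ES cell line, 3 at each of days 0, 2, 4 and 6. Per the labels, total RNA was extracted with a MiniBEST kit, polyadenylated RNA was used, and libraries were made with a SMARTER mRNA-Seq kit. The deposited values are raw counts per gene, and per the submitters' processing notes FastQC 0.11.7, HISAT2 2.1.0, featureCounts 2.0.1, DESeq2 (no version) and the mm10 genome were used, with no role or order given. Strandedness, the treatment of reads with several positions and the annotation release are not stated. The values were checked to be whole numbers. The table gives a symbol and a type for each of 55335 genes, and 212 symbols belong to more than 1 gene. Of the gene IDs, 55154 matched GENCODE release M21, 54587 of them with their version, and coordinates come from there.

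Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts by day (filterByExpr) were kept, which left 16468, and libraries were scaled by TMM. A negative binomial quasi-likelihood model with a coefficient per day was fitted to the 12 libraries together, with robust estimates of spread. The common coefficient of variation was 0.0415 and the median prior degrees of freedom 29.9. Mean totals were 8.67, 11.9, 9.04 and 10.6 times 1e6 counts at days 0, 2, 4 and 6. Between replicates of a day, the chi-square of counts per degree of freedom ran from 1.51 to 3.80, where counting error alone gives 1, over genes with at least 20 counts in the pair.

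Days 2, 4 and 6 were each compared with day 0, day 4 with day 2 and day 6 with day 4, and an F-test took the 4 days together. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 counted as changed, separately for each comparison. SE of fold changes were recovered from the test statistic. Against a day with no count for a gene, a fold is a lower bound set against a floor of 3 counts summed over that day's libraries. With 1 to 3 counts, the CPM ratio is given with its exact 95% counting interval. The first principal components were taken from log2 CPM with a prior count of 2.

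Before the data were examined, 42 gene lists were written from general knowledge, and 41 had at least 4 tested members. Of the clustered protocadherin beta list, 1 of 22 members was tested, so it was left out. Lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, and again with the correlation estimated for each list. Camera asks whether a list moved relative to the other genes. P-values were adjusted over all lists and the 3 comparisons with day 0, and separately over the 2 comparisons of successive days.

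The genes named were also set by a rule made in advance. It takes the 8 largest rises and 8 largest falls against day 0, and 4 and 4 between successive days, among changed genes with at least 5 CPM in the higher day and replicates that do not overlap. Symbols made of Gm, AC, AL, BC or RP and a number, or ending in Rik, were passed over. Other clone names, such as BB287469, were kept. It adds up to 4 members of each list with the smallest p, 24 genes in every comparison whatever their values, and the 6 genes with the smallest F-test p. Results on items withheld for evaluation are not given.

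Alternatives tried were median-ratio factors, upper-quartile factors and library size alone as scaling, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom as tests, and a fit to the 6 libraries of a comparison. Others were a replicate block, counts thinned to the smallest library, adjusted p under 0.01, each library left out in turn, and fry for lists. After the data were seen, a run without Gm42418 and the mitochondrially encoded genes was added. Overlaps of the comparisons with day 0 were set beside 20 simulations with no effect against the same day 0 libraries.

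The procedure was tested on simulated data with the fitted means and spreads, with 50 genes changed at each of 1.25-fold, 1.5-fold, 2-fold and 4-fold. It called 34 to 52% of genes changed 1.25-fold, 62 to 76% at 1.5-fold, 80 to 88% at 2-fold and 94 to 100% at 4-fold, and 7 to 17 of 16253 unchanged genes. A list shifted 1.3-fold was called in all 5 comparisons, and none of the 41 other lists was. Simulated genes were drawn independently and few of them changed, unlike in the real comparisons. These rates therefore need not hold for the data, and the other lists had little chance of a call. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.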

Results

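Polyadenylated RNA was sequenced from mouse embryonic stem (ES) cells at days 0, 2, 4 and 6, with 3 libraries per day and 12 in all. The labels give the same growth conditions for every library: medium with serum replacement and leukaemia inhibitory factor (LIF), a cytokine that holds ES cells in self-renewal, on gelatin with irradiated mouse embryonic fibroblasts. They do not say what was done to the cells from day 0 on. The table held 55335 genes, of which 16468 had enough counts to be tested and 22866 had none in any library. Total counts at day 0 were 9.48, 8.08 and 8.44 times 1e6 for replicates 1, 2 and 3. They were 12.8, 12.3 and 10.6 times 1e6 at day 2, 10.02, 10.2 and 6.95 times 1e6 at day 4, and 13.3, 9.17 and 9.48 times 1e6 at day 6. Levels are counts per 1e6 counts (CPM) as the mean ± SD of the 3 libraries of a day (n = 3), and fold changes are fitted log2 values ± SE. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

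The 12 libraries fell into 4 groups, 1 per day. The first principal component of log2 CPM held 70.5% of the variance and ran from day 0 through days 2 and 4 to day 6. The second, with 16.6%, set day 2 apart from days 0 and 6. The third, with 3.98%, set day 4 apart. Some shares of the counts moved with the days. Mitochondrially encoded genes took 1.61%, 1.43%, 2.43% and 2.00% of counts at days 0, 2, 4 and 6. Gm42418, a gene model that overlaps ribosomal RNA sequence, took 1.43%, 0.332%, 1.54% and 2.82%.

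**Figure D1:**
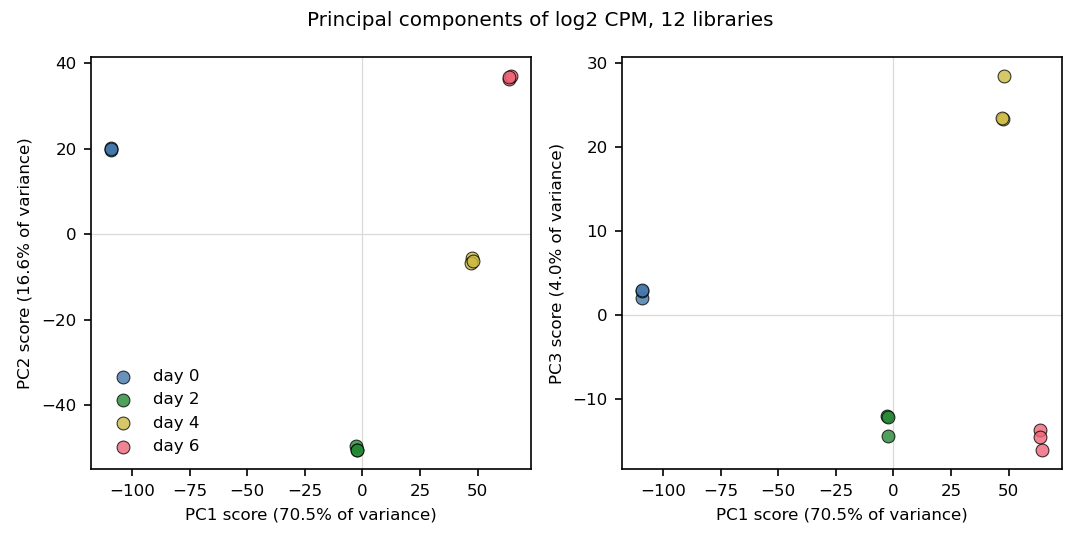
Scores of the 12 libraries on the first 3 principal components of log2 CPM, 1 point per library, coloured by day. The 3 libraries of each day lie together, and the first component, with 70.5% of the variance, orders the days from 0 to 6.

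The comparison of day 2 with day 0 asks what changed first. Genes of pluripotency fell within these 2 days, and Hox genes, known targets of retinoic acid, endoderm genes and genes of the two-cell embryo rose. Cyp26a1 (ENSMUSG00000024987, chromosome 19, 37697798 to 37701536, GRCm38), which encodes a retinoic acid-degrading enzyme, rose 392-fold, from 1.81 ± 0.605 to 728 ± 18.5 CPM (log2 8.61 ± 0.09, adjusted p = 7.89e-43). Tdgf1 (ENSMUSG00000032494, chromosome 9, 110939603 to 110946158), a Nodal co-receptor of pluripotent cells, fell 43.1-fold, from 528 ± 22.4 to 12.2 ± 0.583 CPM (log2 -5.43 ± 0.06, adjusted p = 3.67e-42). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11216 genes (68.1% of those tested) changed, of which 5743 rose and 5473 fell. At least 2-fold changes numbered 1960 up and 1704 down.

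The largest rises were led by the HoxB cluster, whose genes pattern the body axis. Hoxb5 had no count at day 0 and 21.7 ± 1.52 CPM at day 2, at least 175-fold higher, where the floor is 3 counts summed over the libraries of the day. Hoxb8 had 112 ± 4.26 CPM at day 2 against 2 counts at day 0, a CPM ratio of 1359 with a 95% counting interval of 376 to 11228. The ratio was 1074 (367 to 5211) for Hoxb6 and 484 (166 to 2351) for Hoxb2, each with 3 counts at day 0. Such intervals and floors cover counting error only. The antisense gene Hoxb5os was at least 74.1-fold higher, but overlaps coding Hox genes, and the labels do not state stranded counting. Svep1, an extracellular matrix protein gene, was at least 59.9-fold higher, and Csn3, which encodes a casein, at least 55.4-fold. The largest falls were 68.0-fold for Ly6g6e, 65.4-fold for Nphs1 (nephrin, of the kidney filter), 47.1-fold for the keratin gene Krt42 and 45.8-fold for the processed pseudogene Tdgf1-ps1, for which a share of reads from Tdgf1 was not tested. Trp73, of the p53 family, fell 33.6-fold, the glycosyltransferase gene B3gnt3 32.4-fold and the adhesion gene Nectin4 29.5-fold.

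Of 16 core pluripotency genes, 13 fell, 2 rose and 1 did not pass (median log2 -1.12, camera adjusted p = 0.000133). Pou5f1 fell from 1468 ± 43.9 to 655 ± 8.28 CPM (log2 -1.17 ± 0.04, adjusted p = 2.42e-24), Sox2 from 716 ± 11.2 to 181 ± 5.09 CPM, Nanog from 276 ± 3.14 to 82.9 ± 2.96 CPM and Fgf4 from 99.8 ± 4.20 to 6.40 ± 1.62 CPM. Of 17 genes of naive pluripotency, the state of the early epiblast, 15 fell, 1 rose and 1 did not pass (median -1.71, adjusted p = 1.24e-05). Zfp42 fell by 1.86 on the log2 scale, Klf4 by 2.21 and Tfcp2l1 by 1.71, and Esrrb fell 4.29-fold. Among 12 targets of LIF and STAT3, 11 fell and 1 rose (median -1.84, adjusted p = 2.15e-05), with Socs3, a feedback inhibitor of this pathway, going from 129 ± 2.67 to 4.43 ± 1.28 CPM and Icam1 falling 8.44-fold. Among 14 targets of FGF and ERK, 10 fell and 3 rose (median -1.11, adjusted p = 0.0189, and adjusted p = 0.0534 with an estimated correlation). Etv4 fell 6.55-fold and Spry4 5.55-fold, and Phlda1 rose 2.26-fold. Among 13 Wnt targets, 11 fell and 2 rose (median -0.75, adjusted p = 0.0177, and adjusted p = 0.0529 with an estimated correlation). Ccnd1 (cyclin D1) fell 3.48-fold, and the Wnt inhibitor gene Dkk1 rose 11.5-fold. The formative and primed list had no call (9 rose, 5 fell, adjusted p = 0.264). Of its members, Otx2 fell 6.33-fold and Dnmt3a rose 1.71-fold. Fgf5, with 3 counts at day 0, rose to 1.54 ± 0.182 CPM, a ratio of 12.4 (95% counting interval 4.04 to 62.0).

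Of 35 Hox genes tested, 27 rose, 4 fell and 4 did not pass (median 2.85, adjusted p = 4.47e-08). In the HoxB cluster (chromosome 11, 96194316 to 96368256), 9 of 10 rose and none fell; in HoxA (chromosome 6) 9 of 11 rose and 1 fell, in HoxC (chromosome 15) 6 of 8 rose and 2 fell, and in HoxD (chromosome 2) 3 of 6 rose and 1 fell. Hoxa5 rose 29.9-fold. Among 15 retinoic acid targets, 12 rose and 3 fell (median 4.08, adjusted p = 9.38e-06). Besides Cyp26a1, Cyp26b1 went from 0.751 ± 0.374 to 161 ± 7.59 CPM, the receptor gene Rarb from 0.675 ± 0.435 to 64.6 ± 1.85 CPM, and Stra8, a regulator of meiotic entry, from 177 ± 5.99 to 2992 ± 47.9 CPM. This list shares 3 members with other lists.

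Of 16 genes of primitive and visceral endoderm, the extraembryonic layers next to the epiblast, 15 rose and 1 did not pass (median 2.44, adjusted p = 1.94e-08). Dab2 rose 6.20-fold, Cubn 9.85-fold, the laminin gene Lamb1 3.30-fold and the transcription factor gene Gata6 4.01-fold. Mesoderm genes rose in 9 and fell in 2 of 16 cases (median 1.22, adjusted p = 0.0365, and adjusted p = 0.196 with an estimated correlation). Meis1 rose 11.3-fold, Msx1 22.4-fold and Pdgfra 3.11-fold, and Bmp4 fell 5.86-fold. Neuroectoderm genes rose in 7 and fell in 2 of 14 cases (median 1.27, or 0.82 with genes at 0 counts set to their bound, adjusted p = 0.0441, and adjusted p = 0.0818 with an estimated correlation). Pax6 rose by 3.46 on the log2 scale and Sox1 1.83-fold, and the neuronal tubulin gene Tubb3 fell 4.46-fold. Of 4 primitive streak and mesendoderm genes tested, T (brachyury) fell 6.36-fold, while Eomes rose 1.20-fold and Lhx1 5.96-fold. Wnt8a had a log2 value of -0.45 ± 0.22 (adjusted p = 0.0757), and the list had no call (adjusted p = 0.998). The trophectoderm, cardiac muscle, and blood and endothelium lists had no call (adjusted p = 0.667, 0.222 and 0.513). Cdx2, of trophectoderm and posterior mesoderm, was at 0.450 ± 0.261 against 0.170 ± 0.193 CPM (adjusted p = 0.111).

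All 17 tested genes of the two-cell embryo rose (median 3.25, adjusted p = 9.46e-09). Zscan4d went from 5.10 ± 0.306 to 79.1 ± 5.03 CPM, Zscan4a from 5.27 ± 0.667 to 72.6 ± 3.19 CPM, Zscan4b from 2.24 ± 0.469 to 48.0 ± 4.06 CPM and Usp17le from 4.20 ± 0.859 to 50.6 ± 0.892 CPM. These genes have near-identical copies, among which the counting could split reads, so single members are uncertain. Of 20 germline genes, 14 rose and none fell (median 0.72, adjusted p = 0.000459), with Dazl up 4.87-fold, Taf7l 4.17-fold and Brdt 4.24-fold. Of 27 imprinted genes, which are expressed from 1 parental allele, 21 rose and 2 fell (median 1.21, adjusted p = 3.13e-07). Igf2, a fetal growth factor gene, rose 8.89-fold, Mest 7.07-fold, Peg3 6.34-fold and Gnas 2.55-fold. The 4 Y-linked genes rose (median 0.90, adjusted p = 0.0239, and adjusted p = 0.0688 with an estimated correlation), Uty 2.45-fold and Kdm5d 5.67-fold.

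Growth and metabolism genes moved as groups. Of 23 genes of glycolysis and hypoxia, 19 fell and 3 rose (median -0.93, adjusted p = 1.94e-06), among them Pfkp, down 5.63-fold, and the hexokinase genes Hk1 and Hk2, down 4.10-fold and 3.88-fold. Of 21 genes of cholesterol synthesis, 19 rose and 2 fell (median 0.59, adjusted p = 8.85e-05), with Hmgcs1 up 1.80-fold. Of 22 p53 targets, 19 fell and 2 rose (median -0.80, adjusted p = 8.87e-06), with the cell-cycle inhibitor gene Cdkn1a going from 109 ± 2.85 to 29.7 ± 1.21 CPM and the cell-death gene Pmaip1 falling 4.46-fold. S-phase genes fell in 17 and rose in 2 of 23 cases (median -0.36, adjusted p = 0.000234), G2 and mitosis genes fell in 14 and rose in 3 of 20 (median -0.24, adjusted p = 0.00892), and cytosolic ribosomal protein genes fell in 49 and rose in 7 of 77 (median -0.19, adjusted p = 0.000348). Rrm2 fell 2.05-fold, Cenpf 1.81-fold and Rpl8 1.45-fold. Of 10 heat shock genes, 9 fell and 1 rose (median -0.41, adjusted p = 0.00471), with Hsp90aa1 down by 1.07 on the log2 scale.

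The series title names the NuRD complex, a chromatin remodeller with histone deacetylases, and CTCF, which with cohesin shapes chromosome loops. Of 15 NuRD genes, 5 rose, 5 fell and 5 did not pass, and the list had no call (median -0.00, mean 0.10, adjusted p = 0.842). Mbd3 rose from 153 ± 7.89 to 205 ± 11.4 CPM (log2 0.42 ± 0.05, adjusted p = 5.17e-10), Mbd2 2.49-fold and Rbbp7 2.01-fold. Chd5, a neural paralog, fell 2.44-fold, Gatad2b by 0.35, Mta2 by 0.20 and Gatad2a by 0.17 on the log2 scale. Scaling by library size alone moves all day 2 values up by 0.132, so the small falls of Mta2 and Gatad2a depend on the scaling. Log2 values that did not pass were 0.08 ± 0.04 for Chd4 (adjusted p = 0.111), -0.10 ± 0.05 for Hdac1 (adjusted p = 0.0604), 0.03 ± 0.07 for Hdac2 (adjusted p = 0.721) and -0.00 ± 0.04 for Mta1 (adjusted p = 0.934). Of 16 genes of CTCF, cohesin and their regulators, 8 rose and 6 fell, with no call (median 0.10, adjusted p = 0.694). Ctcf (ENSMUSG00000005698, chromosome 8, 105636568 to 105682922) rose from 198 ± 8.88 to 229 ± 6.89 CPM (log2 0.21 ± 0.04, adjusted p = 5.60e-05), and Stag2 rose 1.67-fold, while Zfp143 fell 3.12-fold and Smc1a 1.31-fold. Rad21 stayed at -0.00 ± 0.04 (adjusted p = 0.954). Of 12 DNA methylation genes, 6 fell and 2 rose (median -0.28, adjusted p = 0.0329, and adjusted p = 0.0721 with an estimated correlation), with Tet1 down 7.04-fold, Zfp57 2.88-fold and Dnmt1 1.84-fold. Other remodellers, Polycomb genes, and genes of heterochromatin and retroelement silencing had no call (adjusted p = 0.844, 0.240 and 0.522).

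Camera called 22 of 41 lists, 10 up and 12 down, and 16 of them with an estimated correlation. Adjusted over the list alone, the Hox count was 28 up and 4 down, that of G2 and mitosis 4 up and 14 down, and that of ribosomal proteins 8 up and 49 down; the counts of the other called lists were unchanged. No call was made for replication-dependent histones (adjusted p = 0.158), the integrated stress response (0.810), the unfolded protein response (0.0884), mitochondrially encoded genes (0.0848), interferon response (0.618), epithelial genes (0.667), and targets of Nodal (0.487) and BMP (0.590). Of 23 fibroblast and matrix genes, 9 rose and 9 fell, with no call (median 0.24, or -0.32 with bounds, mean 0.29, adjusted p = 0.968). Fn1 and Col1a1 fell 1.83-fold and 1.97-fold, and Col1a2 rose 6.84-fold. Median, mean and test differed in sign for 7 lists, none of them called, among them Polycomb (median -0.21, mean 0.03, test down) and BMP targets (median -0.00, mean 0.64, test up). Scaled by library size alone, all day 2 values move by 0.132 and the split becomes 7053 up and 4412 down.

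The comparison of day 4 with day 0 asks how far the change had gone by the middle of the series. Pluripotency genes were lower than at day 0, and Hox genes, retinoic acid targets, endoderm and neuroectoderm genes were higher. Igf2 rose 99.4-fold, from 3.23 ± 0.298 to 323 ± 11.5 CPM, and Peg3 20.1-fold, both imprinted and active in fetal growth. Nanog fell 12.3-fold, from 276 ± 3.14 to 22.1 ± 1.83 CPM (log2 -3.62 ± 0.06, adjusted p = 3.69e-36). In all, 12119 genes changed (73.6%), with 6170 up and 5949 down, and 2719 rose and 2151 fell at least 2-fold.

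Hox genes again led the rises. Against no count at day 0, Hoxb5 was at least 152-fold higher, Hoxb5os at least 105-fold, Svep1 at least 109.6-fold and Osr1, a transcription factor gene of early kidney and gut mesoderm, at least 50.6-fold. The CPM ratio was 893 (95% counting interval 247 to 7377) for Hoxb8, 555 (189.6 to 2693) for Hoxb6 and 819 (147 to 32388) for Hoxb3, with 2, 3 and 1 counts at day 0. Nphs1 fell from 11.5 ± 1.14 CPM to no count, at least 107-fold lower. The ratio was 0.00351 (8.85e-05 to 0.0197) for Pou2f3, 0.00548 (0.000138 to 0.0310) for Mst1, 0.00901 (0.00185 to 0.0266) for Ly6g6e, 0.00873 (0.00105 to 0.0319) for Krt42 and 0.0114 (0.00137 to 0.0418) for the water channel gene Aqp5. The immune co-stimulator gene Cd80 fell 76.4-fold and the dynein gene Dnah17 55.9-fold.

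Core pluripotency genes fell in 14 and rose in 1 of 16 cases (median -1.95, adjusted p = 7.69e-06), and naive genes in 16 and 1 of 17 (median -1.96, adjusted p = 2.95e-06). Pou5f1 was down by 2.06, Sox2 by 2.52, Zfp42 by 2.63, Klf4 by 2.39, Esrrb by 3.43, Tfcp2l1 by 2.89 and Tdgf1 by 4.59 in decreases on the log2 scale. Formative and primed genes had no call (6 rose, 9 fell, adjusted p = 0.487): Cdh2 (N-cadherin) rose 13.1-fold and Sox11 5.37-fold, Otx2 fell 24.3-fold and Nodal 9.26-fold, and Fgf5 was at a ratio of 9.35 (95% counting interval 2.93 to 47.7). LIF and STAT3 targets fell in 11 and rose in 1 of 12 cases (median -1.94, adjusted p = 0.000227). FGF and ERK targets fell in 10 and rose in 3 of 14 (median -1.07, adjusted p = 0.0239, and adjusted p = 0.0613 with an estimated correlation), with Spry4 down 12.7-fold. Wnt targets fell in 10 and rose in 2 of 13 (median -1.10, adjusted p = 0.0185, and adjusted p = 0.0534 with an estimated correlation), with Cdx1 down 6.17-fold.

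Of 35 Hox genes, 29 rose and 3 fell (median 3.12, adjusted p = 4.47e-08), and 12 of 15 retinoic acid targets rose and 3 fell (median 3.32, adjusted p = 0.000140), with Cyp26b1 at 351 ± 10.5 CPM and Rarb at 136 ± 2.65 CPM. Endoderm genes rose in 15 and fell in 1 of 16 cases (median 2.73, adjusted p = 3.13e-07): Cubn rose 15.1-fold, Dab2 9.05-fold and Gata6 3.95-fold. Mesoderm genes rose in 13 and fell in 3 of 16 (median 2.78, adjusted p = 0.00292, and adjusted p = 0.0752 with an estimated correlation), with Meis1 up 21.7-fold, Foxf1 48.6-fold and Tbx2 54.0-fold. Neuroectoderm genes rose in 12 and fell in 1 of 14 (median 2.47, adjusted p = 0.00255), with Pax6 up 14.9-fold and Nes 2.23-fold. Trophectoderm genes rose in 9 and fell in 3 of 12 (median 2.11, adjusted p = 0.0387, and adjusted p = 0.0789 with an estimated correlation). The keratin genes Krt8, Krt18 and Krt19, which other epithelia also express, rose 6.00-fold, 6.84-fold and 4.29-fold, Tfap2c fell 14.2-fold, and Cdx2 rose to 0.879 ± 0.174 CPM (adjusted p = 0.00192). T fell 17.6-fold, and its list had no call (adjusted p = 0.413).

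All 17 genes of the two-cell embryo stayed up (median 3.26, adjusted p = 1.47e-07), 17 of 20 germline genes rose and none fell (median 1.10, adjusted p = 7.23e-06), and 23 of 27 imprinted genes rose and 1 fell (median 1.51, adjusted p = 7.25e-08). H19, an imprinted noncoding RNA, rose 25.4-fold. Zscan4e rose 24.1-fold and Dazl 7.89-fold. The 4 Y-linked genes rose (median 0.88, adjusted p = 0.0441, and adjusted p = 0.0938 with an estimated correlation).

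Ribosomal protein genes fell in 70 of 77 cases and none rose (median -0.50, adjusted p = 2.22e-11), and p53 targets fell in 18 of 22, with none up (median -0.83, adjusted p = 2.95e-06), Mdm2 down 2.03-fold and Cdkn1a 4.57-fold. G2 and mitosis genes fell in 17 of 20 (median -0.58, adjusted p = 5.92e-05), S-phase genes in 18 of 23 with 2 up (median -0.46, adjusted p = 0.000375), glycolysis and hypoxia genes in 17 of 23 with 5 up (median -0.68, adjusted p = 0.00169), and heat shock genes in 7 of 10 with 1 up (median -0.31, adjusted p = 0.0239, and adjusted p = 0.0673 with an estimated correlation). Genes of the integrated stress response, which serves amino acid supply, fell in 11 of 17 with 3 up (median -0.67, adjusted p = 0.0158), Slc7a5 down 3.75-fold and Asns 2.68-fold. Cholesterol synthesis genes fell in 14 of 21 with 3 up (median -0.32, adjusted p = 0.0442, and adjusted p = 0.1503 with an estimated correlation), among them Srebf2, the pathway's transcription factor, down 2.14-fold.

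Of 15 NuRD genes, 7 rose and 6 fell (median 0.06, mean -0.01, adjusted p = 0.973). Hdac1 fell from 187 ± 11.4 to 111 ± 4.95 CPM (log2 -0.75 ± 0.05, adjusted p = 2.01e-16), Chd5 4.97-fold, Gatad2a 1.34-fold and Gatad2b 1.35-fold. Rbbp7 rose 2.50-fold, Mbd2 3.05-fold, Hdac2 1.21-fold, Mta1 1.12-fold and Mta2 1.18-fold, Mbd3 rose by 0.38 on the log2 scale, and Chd4 had a log2 value of 0.06 ± 0.05 (adjusted p = 0.221). Of 16 CTCF and cohesin genes, 5 rose and 7 fell (median -0.05, adjusted p = 0.510). Rad21 fell from 968 ± 9.43 to 715 ± 10.4 CPM (log2 -0.44 ± 0.04, adjusted p = 2.54e-12), Smc3 fell 1.66-fold and Wapl 1.48-fold, and Ctcfl, a germline paralog of Ctcf, rose 4.26-fold. Ctcf had a log2 value of 0.08 ± 0.04 (adjusted p = 0.105). DNA methylation genes fell in 9 and rose in 1 of 12 cases (median -0.71, adjusted p = 0.00259), Tet1 11.4-fold and Zfp57 4.37-fold. Polycomb genes had no call (12 fell, 7 rose, median -0.28, adjusted p = 0.244), with Jarid2 down 2.58-fold and Suz12 2.14-fold.

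Camera called 24 lists, 10 up and 14 down, and 17 of them with an estimated correlation. Adjusted over the list alone, the counts of the called lists were the same. Median, mean and test differed in sign for 3 lists with no call, cardiac muscle (median -0.74, mean 0.19, test down), epithelial (median -0.27, mean 0.15, test down) and NuRD. Fibroblast and matrix genes had no call (12 rose, 8 fell, median 0.66, adjusted p = 0.346). Col1a1 was at 6.91 ± 2.24 against 5.89 ± 1.17 CPM (adjusted p = 0.366), Fn1 fell 3.83-fold and Tagln rose 23.3-fold. Scaled by library size alone, day 4 values move by 0.128, and the split becomes 7243 up and 5028 down.

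The comparison of day 6 with day 0 gives the whole change over the series. Pluripotency genes were lower than at day 0, and imprinted, Hox, endoderm, and fibroblast and matrix genes were higher. Igf2 rose 294-fold to 957 ± 40.8 CPM, H19 63.2-fold to 395 ± 13.1 CPM and the collagen gene Col3a1 127-fold to 79.5 ± 5.98 CPM. Fgf4, a growth factor gene of the epiblast, fell 137-fold, from 99.8 ± 4.20 to 0.732 ± 0.123 CPM (log2 -7.10 ± 0.14, adjusted p = 6.68e-34). In all, 12663 genes changed (76.9%), with 6490 up and 6173 down, and 3006 rose and 2272 fell at least 2-fold.

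Against no count at day 0, Svep1 was at least 148-fold higher, Osr1 at least 109-fold, Hoxb5 at least 93.0-fold, the chemokine gene Cxcl10 at least 82.9-fold, the cardiac actin gene Actc1 at least 72.5-fold, the matrix gene Tnc at least 69.3-fold and Dmbt1 at least 58.1-fold. Dmbt1 was matched to its symbol without its ID version. Acta2, smooth muscle actin, reached 63.2 ± 5.47 CPM against 2 counts at day 0, a ratio of 778 (95% counting interval 215 to 6425). With 1 count each at day 6, the ratio was 0.00212 (5.36e-05 to 0.0119) for Cd80, 0.00359 (9.06e-05 to 0.0202) for Trp73, 0.00377 (9.50e-05 to 0.0213) for Krt42, 0.00381 (9.60e-05 to 0.0215) for Nags and 0.00474 (0.000119 to 0.0268) for Capn11. The noncoding RNA gene Platr10 fell 91.1-fold and Tcl1, of naive pluripotency, 90.3-fold.

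Core pluripotency genes fell in 15 and rose in 1 of 16 cases (median -2.10, adjusted p = 9.41e-07) and naive genes in 15 and 1 of 17 (median -2.40, adjusted p = 2.82e-06). Pou5f1 kept 291 ± 14.2 CPM, down 5.04-fold, while Nanog fell 31.9-fold to 8.68 ± 1.33 CPM, Sox2 10.6-fold, Esrrb 17.0-fold, Zfp42 8.13-fold and Klf4 5.06-fold. Formative and primed genes had no call (5 rose, 9 fell, adjusted p = 0.307), with Otx2 down 41.8-fold and Fgf5 at a ratio of 7.08 (95% counting interval 2.19 to 36.4). Targets of FGF and ERK fell in 10 and rose in 3 of 14 cases (median -1.04, adjusted p = 0.0289, and adjusted p = 0.0673 with an estimated correlation), Etv4 34.2-fold. Targets of Wnt fell in 10 and rose in 2 of 13 (median -1.32, adjusted p = 0.0211, and adjusted p = 0.0575 with an estimated correlation), Cdx1 13.3-fold. Targets of Nodal fell in 5 and rose in 2 of 7 (median -1.40, adjusted p = 0.0365, and adjusted p = 0.0810 with an estimated correlation), with Nodal itself down 27.6-fold and its inhibitor gene Lefty2 17.2-fold. LIF and STAT3 targets fell in 8 and rose in 2 of 12 (median -1.61, adjusted p = 0.0189, and adjusted p = 0.146 with an estimated correlation), with Socs3 at 25.5 ± 0.777 CPM. BMP targets rose in 7 and fell in 1 of 9 (median 1.89, adjusted p = 0.0241, and adjusted p = 0.0938 with an estimated correlation), with Id2 up 39.6-fold, Id3 71.6-fold and Gata2 11.7-fold.

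Hox genes rose in 29 and fell in 2 of 35 cases (median 3.10, adjusted p = 3.13e-07), and 12 of 15 retinoic acid targets rose and 3 fell (median 3.10, adjusted p = 0.000428), Meis2 9.56-fold and Cyp26b1 542-fold. Endoderm genes rose in 15 and fell in 1 of 16 (median 2.55, adjusted p = 4.99e-07), with Lamb1 up 5.56-fold and Gata6 4.47-fold. Mesoderm genes rose in 13 and fell in 2 of 16 (median 3.14, adjusted p = 0.00177, and adjusted p = 0.0673 with an estimated correlation), with Foxf1 up 84.0-fold and Tbx2 79.9-fold. Neuroectoderm genes rose in 12 and fell in 2 of 14 (median 2.59, adjusted p = 0.00726), with Pax6 up 14.1-fold and Dcx, of migrating neurons, at least 47.8-fold. Trophectoderm genes rose in 9 and fell in 3 of 12 (median 2.96, adjusted p = 0.0299, and adjusted p = 0.0691 with an estimated correlation), with Krt18 up by 3.70 on the log2 scale and Cdx2 15.1-fold, to 2.66 ± 0.523 CPM. T fell 24.7-fold, and its list had no call (adjusted p = 0.335).

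Of 23 fibroblast and matrix genes, which both feeder cells and differentiating mesoderm express, 16 rose and 6 fell (median 1.74, adjusted p = 0.0158). Col1a1 rose from 5.89 ± 1.17 to 36.8 ± 2.26 CPM (log2 2.65 ± 0.14, adjusted p = 2.26e-17), Tagln 42.2-fold, and fibronectin, Fn1, fell 3.83-fold. Two-cell genes were up in 15 of 17 cases and none fell (median 1.93, adjusted p = 0.000115), with Zscan4d at 26.7 ± 0.208 CPM. Germline genes rose in 17 of 20, with none down (median 0.96, adjusted p = 2.15e-05), and imprinted genes in 22 of 27, with none down (median 1.84, adjusted p = 9.07e-08), Meg3 11.7-fold. The 4 Y-linked genes rose (median 1.03, adjusted p = 0.0272, and adjusted p = 0.0721 with an estimated correlation).

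Ribosomal protein genes fell in 73 of 77 cases, with none up (median -0.54, adjusted p = 6.42e-12), S-phase genes in 21 of 23 with 1 up (median -0.56, adjusted p = 1.14e-05) and G2 and mitosis genes in 19 of 20, with none up (median -0.52, adjusted p = 2.02e-05). Rps2 fell 2.12-fold, Rrm2 2.89-fold and Cenpf 2.20-fold. Cholesterol synthesis genes fell in 17 of 21 with 3 up (median -0.64, adjusted p = 0.000898), Msmo1 2.57-fold. Integrated stress response genes fell in 13 of 17 with 3 up (median -0.76, adjusted p = 0.00220), Asns 4.23-fold. Heat shock genes fell in 8 of 10 with 1 up (median -0.72, adjusted p = 0.00321), p53 targets in 16 of 22 with 1 up (median -0.65, adjusted p = 0.000410), and glycolysis and hypoxia genes in 16 of 23 with 7 up (median -0.56, adjusted p = 0.0120). Eno1 fell 3.15-fold, whereas P4ha1, a collagen-modifying enzyme gene of the hypoxia response, rose 3.36-fold. Cdkn1a fell 2.94-fold.

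Of 15 NuRD genes, 8 rose and 5 fell (median 0.14, adjusted p = 0.774). Hdac1 fell from 187 ± 11.4 to 75.3 ± 4.44 CPM (log2 -1.31 ± 0.05, adjusted p = 7.47e-24), Chd5 6.50-fold and Gatad2a 1.35-fold. Rbbp7 rose 3.22-fold, Mbd2 4.28-fold, Hdac2 1.22-fold, Mta1 1.26-fold, Mta2 1.26-fold and Mbd3 1.16-fold. Chd4 (ENSMUSG00000063870, chromosome 6, 125095981 to 125130591), the ATPase of the complex, rose 1.10-fold (log2 0.14 ± 0.05, adjusted p = 0.00584) and Gatad2b 1.11-fold. Of 16 CTCF and cohesin genes, 6 rose and 7 fell (median -0.04, mean 0.04, adjusted p = 0.747). Rad21 fell from 968 ± 9.43 to 635 ± 5.43 CPM (log2 -0.61 ± 0.04), Smc3 fell 1.67-fold and Stag2 rose 1.64-fold. Ctcf had a log2 value of -0.05 ± 0.04 (adjusted p = 0.326). DNA methylation genes fell in 9 and rose in 3 of 12 (median -0.85, adjusted p = 0.0158, and adjusted p = 0.0513 with an estimated correlation), with Dnmt3b down 2.47-fold and Uhrf1 1.89-fold. Polycomb genes had no call (7 rose, 11 fell, median -0.41, mean 0.02, test down, adjusted p = 0.357).

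Camera called 27 lists, 12 up and 15 down, and 18 of them with an estimated correlation, and counts adjusted over the list alone were the same in the called lists. Median, mean and test differed in sign for 3 lists with no call, cardiac muscle (median -0.93, mean 0.46, test down), CTCF and cohesin, and Polycomb. Interferon response genes, among them Cxcl10, had no call (12 rose, 5 fell, median 0.92, adjusted p = 0.307). Scaled by library size alone, day 6 values move by 0.104, and the split becomes 7201 up and 5446 down.

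**Figure D2:**
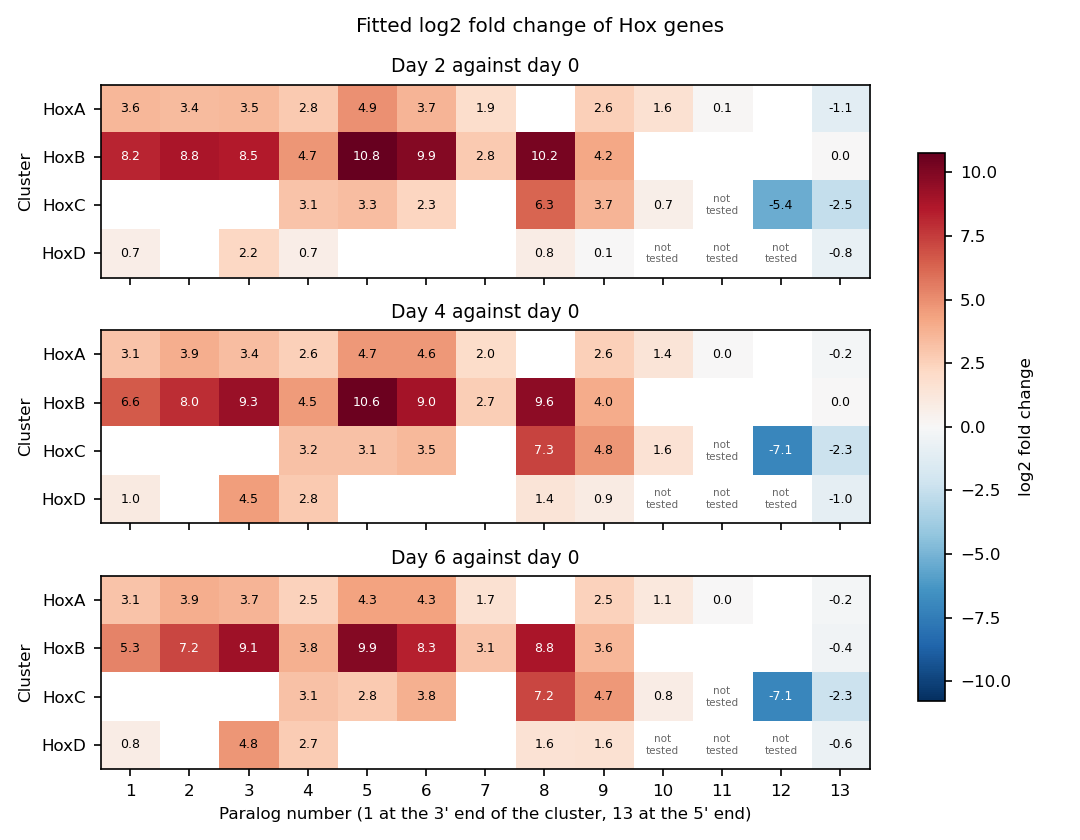
Fitted log2 fold change against day 0 of the Hox genes tested, by cluster (vertical) and paralog number (horizontal), at days 2, 4 and 6. HoxB genes show the largest values, and values for genes with few or no counts at day 0, such as Hoxb5, depend on the prior count and are no bounds.

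**Figure D3:**
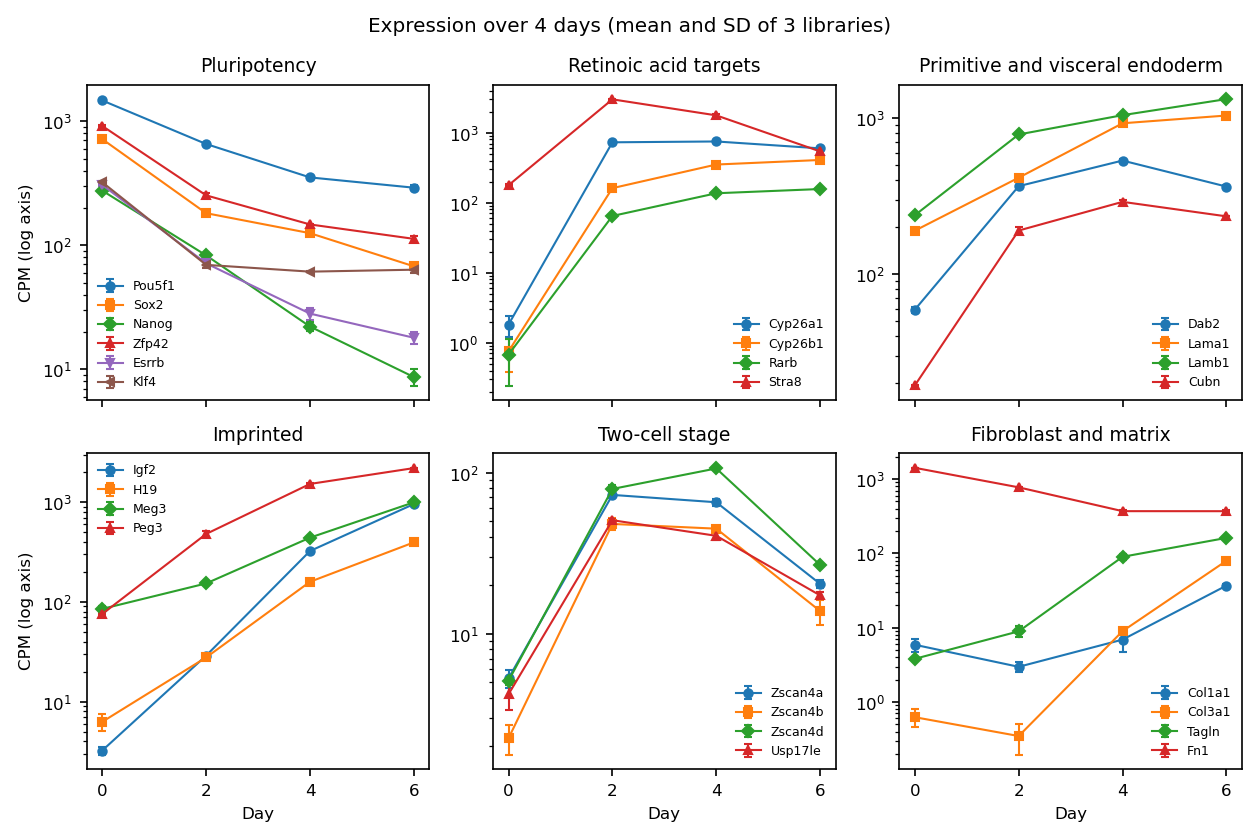
CPM by day on a log axis for genes of 6 groups, points the mean and bars the SD of 3 libraries. Pluripotency genes fall from day 0, retinoic acid targets and two-cell genes rise by day 2, and Igf2 and Col3a1 keep rising to day 6.

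The comparison of day 4 with day 2 asks what changed after the first response. Cholesterol synthesis and ribosomal protein genes fell, and unfolded protein response genes and imprinted genes rose. Ecm1, an extracellular matrix gene, rose 31.3-fold, from 1.84 ± 0.310 to 58.7 ± 4.49 CPM (log2 4.97 ± 0.11, adjusted p = 6.47e-31). Nepn rose 36.6-fold, Osr1 35.4-fold and Foxc2, a mesoderm transcription factor gene, 30.8-fold. The largest falls were 6.22-fold for Cacng6, 5.95-fold for the nucleotidase gene Nt5e, 5.36-fold for Rps12-ps4, a processed pseudogene within the span of Nphs1, for which a share of reads from other genes was not tested, and 4.80-fold for Tll1. In all, 8245 genes changed (50.1%), with 4167 up and 4078 down, and 988 rose and 558 fell at least 2-fold.

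Core pluripotency genes fell in 11 and rose in 3 of 16 cases (median -0.53, adjusted p = 0.000339) and naive genes in 13 and 1 of 17 (median -0.78, adjusted p = 0.000107). Nanog fell 3.71-fold, Esrrb 2.51-fold, Pou5f1 1.86-fold, Zfp42 1.71-fold, Sox2 1.45-fold and Klf4 1.13-fold, while Tdgf1 rose 1.79-fold from its day 2 level. Formative and primed genes fell in 11 and rose in 2 of 16 (median -0.90, adjusted p = 0.00283, and adjusted p = 0.0635 with an estimated correlation), Dnmt3a 1.87-fold and Otx2 3.84-fold, and Fgf5 had a log2 value of -0.41 ± 0.33 (adjusted p = 0.316). Nodal targets fell in 5 and rose in 1 of 7 (median -0.89, adjusted p = 0.00649), Lefty2 3.88-fold. BMP targets rose in 6 and none fell of 9 (median 1.09, adjusted p = 0.0142, and adjusted p = 0.0841 with an estimated correlation), Id3 4.77-fold and Id1 3.13-fold. LIF and STAT3, FGF and ERK, and Wnt targets had no call (adjusted p = 0.793, 0.793 and 0.0653), with Socs3 up 2.49-fold, Egr1 up 5.34-fold and Cdx1 down 4.08-fold.

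Mesoderm genes rose in 11 and fell in 2 of 16 cases (median 0.81, adjusted p = 0.000900, and adjusted p = 0.0643 with an estimated correlation), with Foxf1 up 14.6-fold and Tbx2 5.72-fold. Endoderm genes rose in 11 and fell in 4 of 16 (median 0.58, adjusted p = 0.00601, and adjusted p = 0.0515 with an estimated correlation): Lama1 rose 2.23-fold and the serum lipoprotein gene Apoa1 4.73-fold, Apoe fell 2.02-fold, and Gata6 had a log2 value of -0.02 ± 0.06 (adjusted p = 0.795). Neuroectoderm genes rose in 9 and fell in 1 of 14 (median 0.68, adjusted p = 0.00156), Pax6 1.36-fold, and trophectoderm genes rose in 8 and fell in 1 of 12 (median 1.23, adjusted p = 0.000777), Krt19 6.13-fold and Gata3 4.98-fold. T and Cdx2 had log2 values of -1.47 ± 0.63 (adjusted p = 0.0501) and 1.02 ± 0.48 (adjusted p = 0.0773). Imprinted genes rose in 18 and fell in 3 of 27 (median 0.33, adjusted p = 8.71e-06), Igf2 11.2-fold, and germline genes rose in 13 of 20, with none down (median 0.41, adjusted p = 0.000107). Hox genes and retinoic acid targets had no call (adjusted p = 0.429 and 0.217), and of the HoxB genes 1 rose and 5 fell, Hoxb6 1.93-fold and Hoxb1 2.96-fold. Two-cell genes had no call either (3 rose, 7 fell, adjusted p = 0.791). The fibroblast and matrix list had no call (10 rose, 5 fell, median 0.27, adjusted p = 0.0949), with Col1a1 up 2.26-fold and Tagln 9.95-fold.

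Of 21 cholesterol synthesis genes, 19 fell and 1 rose (median -0.80, adjusted p = 3.62e-11), Hmgcs1 2.27-fold. Ribosomal protein genes fell in 61 and rose in 1 of 77 cases (median -0.33, adjusted p = 6.71e-13), integrated stress response genes fell in 13 and rose in 2 of 17 (median -0.62, adjusted p = 2.49e-05), and G2 and mitosis genes fell in 15 and rose in 2 of 20 (median -0.28, adjusted p = 0.000126). p53 targets fell in 13 and rose in 3 of 22 (median -0.20, adjusted p = 0.0311, and adjusted p = 0.0658 with an estimated correlation), with Cdkn1a down by 0.32 on the log2 scale. Unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, rose in 13 of 15, with none down (median 0.36, adjusted p = 5.68e-05), Manf 1.73-fold and Hspa5 1.42-fold. Glycolysis and hypoxia genes rose in 13 and fell in 3 of 23 (median 0.18, adjusted p = 0.00847), Ldha 1.84-fold and P4ha1 2.29-fold. Mitochondrially encoded genes rose in 7 of 13, with none down (median 0.53, adjusted p = 0.000297), mt-Co1 2.40-fold, while their share of counts went from 1.43% to 2.43% and that of Gm42418 from 0.332% to 1.54%.

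Genes of CTCF, cohesin and their regulators fell in 9 and rose in 1 of 16 cases (median -0.13, adjusted p = 0.0326, and adjusted p = 0.136 with an estimated correlation). Rad21 fell 1.35-fold (log2 -0.43 ± 0.04, adjusted p = 1.12e-11), Smc3 1.44-fold, Nipbl 1.33-fold and Ctcf 1.10-fold (log2 -0.13 ± 0.04, adjusted p = 0.0109), and Ctcfl rose 1.95-fold. Other chromatin remodellers fell in 14 and rose in 1 of 20 (median -0.22, adjusted p = 0.000900, and adjusted p = 0.0635 with an estimated correlation), Chd9 1.81-fold and Smarca5 1.35-fold. Silencing genes fell in 9 of 15, with none up (median -0.13, adjusted p = 0.00880), Cbx3 2.00-fold and Trim28, the KAP1 co-repressor, 1.32-fold. DNA methylation genes fell in 7 and rose in 2 of 12 (median -0.26, adjusted p = 0.0311, and adjusted p = 0.0757 with an estimated correlation). The NuRD list had no call (5 rose, 6 fell, median -0.04, adjusted p = 0.475): Hdac1 fell 1.57-fold and Gatad2a 1.19-fold, and Mta2 rose 1.36-fold, Hdac2 1.19-fold and Mta1 1.13-fold. Chd4, Mbd3 and Gatad2b had log2 values of -0.02 ± 0.04, -0.04 ± 0.05 and -0.08 ± 0.06 (adjusted p = 0.749, 0.490 and 0.304).

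Camera called 23 lists, 10 up and 13 down, and 15 of them with an estimated correlation. Median, mean and test differed in sign for 6 lists with no call, among them cardiac muscle (median -0.05, mean 0.64, test up). Adjusted over the list alone, counts of called lists changed to 9 up and 1 down for trophectoderm, 14 and 0 for germline, 1 and 10 for CTCF and cohesin, 13 and 4 for glycolysis, and 1 and 62 for ribosomal proteins.

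The comparison of day 6 with day 4 asks what was still changing at the end. Genes of the two-cell embryo fell, and collagen, matrix, epithelial and interferon response genes rose. Col3a1 rose 8.84-fold, from 8.98 ± 0.156 to 79.5 ± 5.98 CPM (log2 3.14 ± 0.09, adjusted p = 2.56e-27), and the water channel gene Aqp1 9.61-fold (log2 3.26 ± 0.13), with Tnc up 7.36-fold and the muscle troponin gene Tnni2 6.77-fold. Zscan4c fell 4.17-fold (log2 -2.06 ± 0.10, adjusted p = 2.99e-20), Zscan4-ps1 and Zscan4-ps3, annotated as protein-coding, 4.68-fold and 4.40-fold, and BB287469 5.37-fold. In all, 7065 genes changed (42.9%), with 3893 up and 3172 down, and 505 rose and 419 fell at least 2-fold.

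Of 17 genes of the two-cell embryo, 16 fell and none rose (median -1.68, adjusted p = 5.43e-12). Zscan4d went from 106 ± 1.37 to 26.7 ± 0.208 CPM and Zscan4a fell 3.24-fold, with the same limit on near-identical copies. Of 23 fibroblast and matrix genes, 18 rose and none fell (median 0.81, adjusted p = 3.50e-06): Col1a1 rose 5.48-fold, from 6.91 ± 2.24 to 36.8 ± 2.26 CPM, Col1a2 3.37-fold, Acta2 3.32-fold and the matrix protease gene Mmp2 3.14-fold. With them the share of Gm42418 went from 1.54% to 2.82%. Epithelial genes rose in 9 of 12, with none down (median 0.41, adjusted p = 0.000165), Cldn7 2.31-fold and Epcam 1.55-fold. Interferon response genes rose in 9 of 19, with none down (median 0.41, adjusted p = 0.00649), Cxcl10 3.18-fold. Imprinted genes rose in 17 and fell in 6 of 27 (median 0.29, adjusted p = 0.00283), Igf2 2.96-fold and Dlk1 2.68-fold. Mesoderm genes rose in 9 of 16, with none down (median 0.45, adjusted p = 0.0126, and adjusted p = 0.132 with an estimated correlation), endoderm genes rose in 11 and fell in 3 of 16 (median 0.39, adjusted p = 0.0311, and adjusted p = 0.0951 with an estimated correlation), and trophectoderm genes rose in 7 and fell in 1 of 12 (median 0.37, adjusted p = 0.0218, and adjusted p = 0.0643 with an estimated correlation). Apoa1 rose 3.01-fold, Gata6 1.13-fold, Cdx2 2.92-fold and Foxc1 2.54-fold, and Dab2 fell 1.47-fold. Hox genes fell in 12 and rose in 4 of 35 (median -0.08, adjusted p = 0.0472, and adjusted p = 0.143 with an estimated correlation), Hoxb8 1.77-fold. Pax6, T and Otx2 had log2 values of -0.08 ± 0.10, -0.49 ± 0.87 and -0.78 ± 0.45 (adjusted p = 0.520, 0.687 and 0.170).

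Core pluripotency genes fell in 10 and rose in 2 of 16 cases (median -0.33, adjusted p = 0.000153), Nanog 2.59-fold, Sox2 1.85-fold and Pou5f1 1.21-fold, while Tdgf1 rose 2.29-fold. Naive genes fell in 8 and rose in 1 of 17 (median -0.39, adjusted p = 0.00649, and adjusted p = 0.0643 with an estimated correlation), Esrrb 1.58-fold and Zfp42 1.31-fold, and Klf4 had a log2 value of 0.06 ± 0.06 (adjusted p = 0.448). Formative and primed genes fell in 5 and rose in 1 of 16 (median -0.16, adjusted p = 0.0489, and adjusted p = 0.168 with an estimated correlation), and Fgf5 had a value of -0.40 ± 0.38 (adjusted p = 0.424). LIF and STAT3 targets rose in 7 and fell in 1 of 12 (median 0.46, adjusted p = 0.00379, and adjusted p = 0.0879 with an estimated correlation), Bcl3 3.04-fold, Socs3 2.33-fold and Stat3 itself 1.54-fold. BMP targets rose in 7 of 9, with none down (median 0.60, adjusted p = 0.00563, and adjusted p = 0.0635 with an estimated correlation), Gata2 4.28-fold. p53 targets rose in 13 and fell in 2 of 22 (median 0.30, adjusted p = 0.00649), with Cdkn1a up from 23.9 ± 2.88 to 37.1 ± 0.215 CPM. S-phase genes fell in 13 and rose in 1 of 23 (median -0.19, adjusted p = 0.000689), integrated stress response genes in 11 and 1 of 17 (median -0.38, adjusted p = 0.000650), cholesterol synthesis genes in 15 and 3 of 21 (median -0.28, adjusted p = 0.000153), and heat shock genes in 8 of 10, with none up (median -0.35, adjusted p = 0.000193). Msmo1 fell 1.99-fold, Asns 1.58-fold, Tyms 1.58-fold and Hspa8 1.61-fold.

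The NuRD list had no call (5 rose, 5 fell, median 0.01, adjusted p = 0.861): Hdac1 fell 1.47-fold and Mbd3 1.12-fold, and Gatad2b rose 1.49-fold, Mbd2 1.41-fold and Mta1 1.12-fold. Chd4, Hdac2, Mta2 and Gatad2a had log2 values of 0.08 ± 0.04, 0.01 ± 0.07, 0.10 ± 0.05 and -0.01 ± 0.04 (adjusted p = 0.169, 0.935, 0.155 and 0.847). The CTCF and cohesin list had none either (7 rose, 3 fell, median 0.07, adjusted p = 0.306), with Nipbl up 1.29-fold, Rad21 down 1.13-fold and Ctcf down 1.09-fold (log2 -0.13 ± 0.04, adjusted p = 0.0169). Camera called 19 lists, 10 up and 9 down, and 11 of them with an estimated correlation. Median, mean and test differed in sign for 2 lists with no call, Polycomb and Nodal targets. Adjusted over the list alone, the counts became 0 up and 17 down for two-cell genes, 10 and 0 for mesoderm and for interferon response, 12 and 3 for endoderm, 0 and 5 for formative genes, 17 and 7 for imprinted genes, 1 and 15 for S phase, 0 and 9 for heat shock, 3 and 16 for cholesterol, and 8 and 0 for BMP targets.

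**Figure D4:**
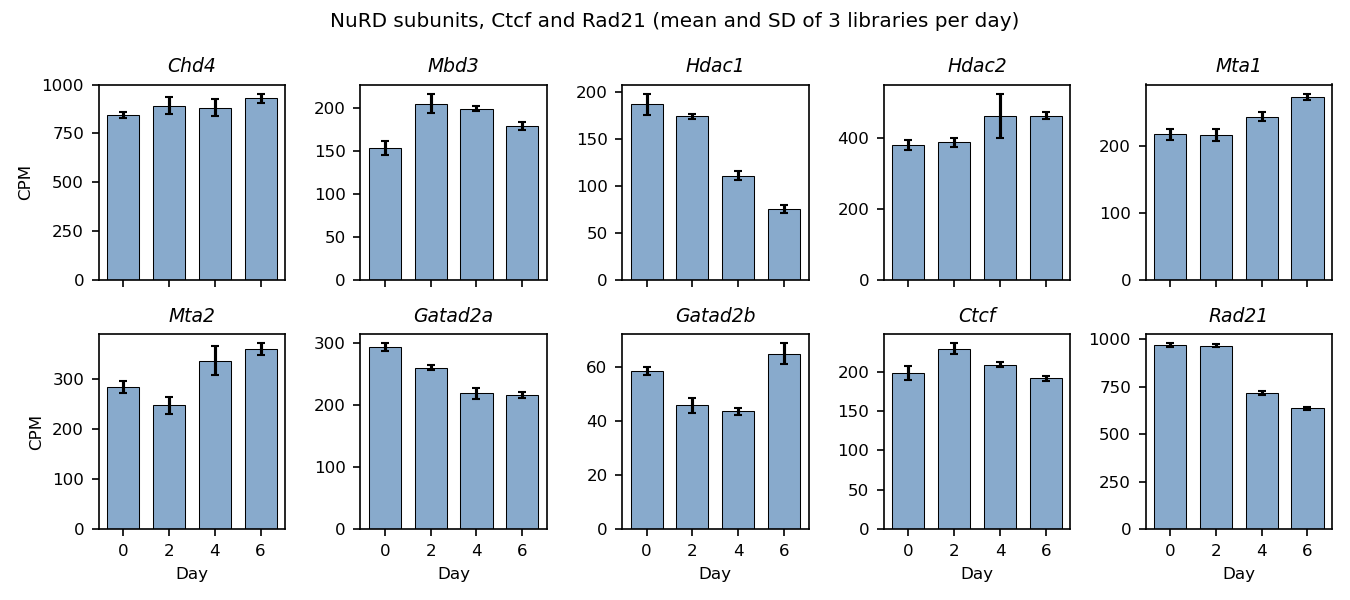
CPM by day of 8 NuRD subunit genes, Ctcf and Rad21, bars the mean and error bars the SD of 3 libraries. Hdac1 and Rad21 are lower at day 6 than at day 0, and Chd4 and Ctcf move little.

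Over the 4 days together, the F-test of edgeR called 14685 genes (89.2%). The 6 with the smallest p were Igf2 (3.23, 28.9, 323 and 957 CPM at days 0, 2, 4 and 6), Tdgf1 (528, 12.2, 22.0 and 50.4), Cyp26a1 (1.81, 728, 748 and 596), H19 (6.27, 27.7, 159 and 395), Clu (14.8, 29.6, 191 and 376) and Peg3 (75.6, 480, 1522 and 2195). Their adjusted p-values ran from 2.71e-46 to 1.10e-41. Clu encodes a secreted chaperone, and Peg3 was matched to its symbol without its ID version.

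Of the genes called, 8271 moved from day 0 in the same direction at days 2, 4 and 6, 4186 up and 4085 down, and 2742 did so at least 2-fold. No gene did so with unchanged groups simulated against the same day 0 libraries. There, any 2 comparisons shared at most 1 call, so that result was near certain. It does not show how much of the real overlap comes from the shared controls. Days 2 and 4 shared 4675 rises and 4551 falls where independent lists would share 2152 and 1977. Days 2 and 6 shared 4465 and 4339 (independent 2263 and 2052), and days 4 and 6 shared 5320 and 5180 (independent 2432 and 2230). Fold changes across genes had Pearson correlations of 0.888, 0.797 and 0.943 for these pairs, against 0.560, 0.577 and 0.543 simulated with no effect, and covariances of 1.52, 1.48 and 2.21 against 0.0179, 0.0179 and 0.0178. The simulated covariances lie far below the real ones, which argues against spread between the day 0 libraries as a large part of the excess. A feature common to all day 0 libraries would not show in the simulation. These libraries are too few to be split, so part of the excess may come from such a feature. The day 0 to 2 change and the day 4 to 6 change, which share no library, had r = -0.062 and rho = -0.008 across genes, which are not independent replicates.

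**Figure D5:**
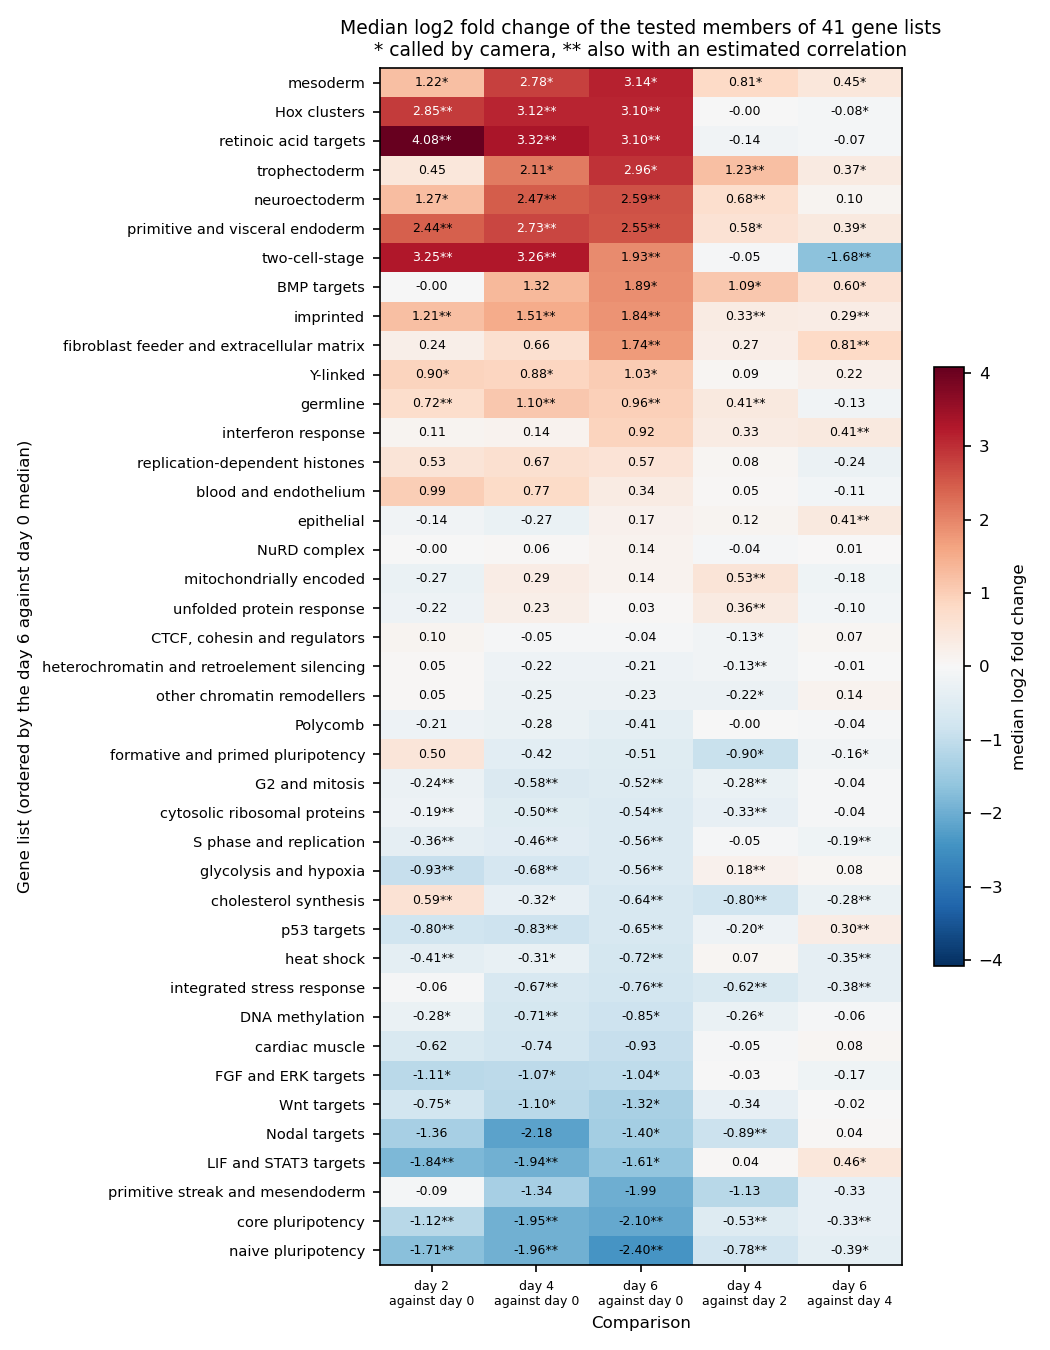
Median log2 fold change of the tested members of 41 gene lists (vertical) in the 5 comparisons (horizontal), with 1 star where camera called the list and 2 where it also did with an estimated correlation. Two-cell genes run from 3.25 at day 2 to a fall of 1.68 on the log2 scale from day 4 to day 6.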

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

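The tests of the lists below, and those of the retinoic acid target, two-cell and matrix patterns, were chosen only after the results were seen. The tests on other groupings of the libraries were planned.

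For 5 lists, camera with its preset correlation called the change from day 0 to day 2 and that from day 4 to day 6 in opposite directions, and its test of the difference between these changes passed. The adjusted p of that test was 1.40e-11 for two-cell genes (medians 3.25 and then -1.68), 5.97e-09 for Hox genes (2.85 and -0.08), 1.41e-06 for p53 targets (-0.80 and 0.30), 9.88e-07 for cholesterol synthesis (0.59 and -0.28) and 6.32e-06 for LIF and STAT3 targets (-1.84 and 0.46). A pass was near certain for lists picked by opposite calls in the same data, so it adds little to those calls. With an estimated correlation the adjusted p was 0.00484 for the first 3, 0.0122 for cholesterol synthesis and 0.0271 for LIF and STAT3 targets. The calls from day 4 to day 6 were lost for Hox genes (adjusted p = 0.143 with an estimated correlation) and for LIF and STAT3 targets (0.0879). Among lists called in the first step alone, the difference between steps also passed for retinoic acid targets (medians 4.08 and -0.07, adjusted p = 3.24e-07), glycolysis and hypoxia (-0.93 and 0.08, 1.79e-07) and germline genes (0.72 and -0.13, 0.000560). Groups of 3 libraries were not tested for libraries that stand apart.

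Retinoic acid targets rose at day 2 (median 4.08, with 12 of 15 up and 3 down). Of 23 fibroblast genes, 9 rose and 9 fell. Their median was 0.245 (median absolute deviation 1.51), or -0.32 with bounds. It lay below the median of the retinoic acid targets by more than this deviation. This argues only against feeder RNA that rose as much as these targets, and a smaller feeder contribution could not be decided. Other cells express the fibroblast genes too, so their list is no pure measure of feeder RNA. Scaling is argued against, as leaving out composition factors shifts all genes by 0.132, while the list median was 4.08 with them and 4.21 without. The spread of this median was put at 0.710 from the deviations of its members, which treats genes as independent. Retinoic acid signalling in the cultures after day 0 stays open as a hypothesis, since the labels name no treatment and it cannot be told apart from other causes: across 33 Hox genes outside the list, the rise fell with paralog number (Spearman rho -0.556, permutation p = 0.00088), but not among the 25 with numbers 1 to 9 (rho -0.0325, permutation p = 0.878), so the order rests on paralogs 10 to 13, and neighbours in a cluster are not independent. The first tests run here were the place of the list among 10000 random lists (highest random median 0.712), which only restates the pattern, and the share of fibroblast genes that rose (39.1%, exact 95% interval 19.7 to 61.5), which did not decide, and both were replaced; a look at Col1a1, Col6a1 and Fn1 alone, picked by their values, was not used.

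Two-cell genes rose at day 2 and fell from day 4 to day 6. For the Zscan4 family, reads moved among its near-identical copies are argued against. Its 9 genes summed had 26.0 ± 1.80, 416 ± 7.77, 419 ± 17.1 and 113 ± 4.15 CPM at days 0, 2, 4 and 6 (log2 ratio 4.00 at day 2 and -1.89 from day 4 to day 6). Other copied genes of the list, such as Usp17le, were not summed. With all libraries thinned to 1 total, the medians over 16 members were 3.17 and -1.55, so unequal depth was not needed for these changes. CPM already scale by depth, so changes of this size were bound to last. A smaller share of cells in a two-cell-like state at day 6 cannot be told apart from lower expression per cell: members fell by amounts with an SD of 0.542 against a median SE of 0.121, and unequal falls can come from either.

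Fibroblast and matrix genes rose from day 4 to day 6 (median 0.81, with 18 of 23 up and 0 down). Uneven carry-over of other cells among the day 6 replicates stays open: the largest coefficient of variation of Col1a1, Col3a1, Acta2 and Tagln, picked after their values were seen, was 8.66%, which decides nothing if replicates are technical. RNA from feeder fibroblasts, which the labels name in the culture, cannot be told apart from expression by the ES-derived cells: of 8 members under 5 CPM at day 4, 5 rose (62.5%, exact 95% interval 24.5 to 91.5), and both cell types express these genes. No biological explanation was tested.

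Each pair of days was regrouped in all 10 ways of 3 against 3, and for each count in turn 1 of the 10, the real one, gave a value as large. The groupings are too few for a share under 0.05. In the order day 2, 4 and 6 against 0, 4 against 2 and 6 against 4, real counts of changed genes were 11216, 12119, 12663, 8245 and 7065, and edgeR gave 0 in each of the 9 others, with at most 394, 320, 247, 625 and 647 at an unadjusted p under 0.05. Counts of at least 2-fold changes were 3664, 4870, 5278, 1546 and 924 against 0. Lists called were 22, 24, 27, 23 and 19, against at most 17, 17, 16, 12 and 11. Each other grouping puts 2 libraries of a day with 1 of the other day, so it keeps part of the difference between days and adds it to the spread, and neither its lists nor its 0 genes show what the tests give with no effect. For the F-test, 1 of 100 groupings of the 12 libraries, the real one, reached 14685 genes (highest other 11765). The share is under 0.05, which argues against chance in how these libraries were grouped but does not exclude it. It does not bear on differences between single cultures, if the replicates are technical.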

How the results depend on the processing

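Leaving out Gm42418 and the mitochondrially encoded genes was chosen after the data were seen; the other alternatives were planned. With an estimated correlation 15 lists were called for day 4 against 2 and 11 for day 6 against 4. Fry called 35, 37 and 38 lists for days 2, 4 and 6 against 0, 35 for 4 against 2 and 31 for 6 against 4. Fry asks whether a list changed at all, not relative to the other genes as camera does. With 42.9 to 76.9% of tested genes changed, many lists can pass it, so its calls are no firmer support. At least 2-fold, the overlap at all 3 days was 2742 genes. Library size alone moves all day 2 values by 0.132, so Mta1 and Rad21, near 0 before, turned to log2 values of 0.127 and 0.129 and gained a call. Among the other values of named genes, this scaling lost 3 calls and gained 4. The correlation of the first and last steps ran from -0.0667 to -0.0455 with 1 library left out, moving most without day 6 replicate 1 (-0.0455) and day 6 replicate 3 (-0.0537). Over 21891 values of named genes, 21771 kept the call or its absence, 88 lost the call, 30 gained it and 2 turned. Over 3890 values of lists, 3755 kept it, 66 lost it, 69 gained it and 0 turned. Of these, the estimated correlation alone lost 38 calls and fry gained 61. At least 1 alternative changed the call for 99 of 205 list results, against 37 of 914 for named genes. A change of sign counted as a turn for a gene only if either fit called it. For a list it counted only if both fits called the list, so other changes of sign are not in these numbers. No pairing of libraries by replicate number was detected (same-number r from -0.081 to 0.103 over 18 pairs, other-number r from -0.139 to 0.114 over 36). This does not show that same-numbered libraries share no culture or date. With a replicate block changed genes were 11195, 12075, 12630, 8180 and 7004, lists 22, 25, 27, 23 and 18, and F-test genes 14635. Without Gm42418 and mitochondrial genes, changed genes were 11192, 12094, 12641, 8227 and 7046.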

Other observations

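The test of Hox position below was chosen only after the result was seen.

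The median of genes on the X chromosome lay above that of each autosome at each later day. The median log2 fold change of 444 X-linked genes against day 0 was 0.262, 0.326 and 0.384 at days 2, 4 and 6. Medians of single autosomes ran from -0.0849 to 0.143, from -0.103 to 0.125 and from -0.104 to 0.157. This was not tested, and neighbouring genes are not independent.

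Hox genes near the 3' end of their clusters seemed to peak early, as Hoxb1 fell from day 2 to day 4 and again to day 6. A role of position in the time course could not be shown: across 35 Hox genes, paralog number and the change from day 2 to day 6 had a Spearman rho of 0.107 (permutation p = 0.538). Over the 25 genes with at least 5 CPM rho was 0.176 (permutation p = 0.396).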
